A study of Arabidopsis thaliana with 17 samples.

How the data were processed

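RNA was measured in 17 libraries of Arabidopsis root cells in 6 groups. Per the labels' protocols, total RNA was extracted with TRIzol after disruption in a mill, cleaned with chloroform and a micro column kit, selected for poly(A) tails, made into libraries with a directional kit and sequenced as paired-end reads of 150 bases. Poly(A) selection limits what organelle transcripts can show, since most of them lack long poly(A) tails. Per the submitters' processing notes, HISAT2 and Cufflinks were used; their versions, settings and the genome build are not given in the sources used here. Whether counting used the strand is also not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies such as small heat shock, LHCB and histone genes.

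A first deposited table holds 1 FPKM column per library, with 33560 rows. A second, of 33201 rows, holds 1 FPKM per group, pooled by the authors, and for 7 comparisons a log2 ratio and a q-value, as its column names show. The FPKM values were normalized by the authors to transcript length and mapped fragments, as the unit's name says. How the q-values were made by the authors is not given in the sources used here. Of the group table's entries, 282 join several gene IDs. Of 32919 single IDs, 32218 matched the TAIR10.1 reference, which was used for names only, and 10458 had a symbol there. No coordinates are given, because the authors' build is not given in the sources used here.

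The planned tests were limma on log2 FPKM per library, camera for gene lists, and fits with a replicate block or with each replicate left out. They were not run, since the library columns do not keep 1 gene per line. Over all 136 pairs of libraries, the median correlation of log2(FPKM + 1) was 0.290 line by line (0.159 to 0.586), 0.815 for means over 10 neighbouring lines, 0.997 over 500 lines and 0.998 with each library sorted by value. The 16 pairs within a group gave 0.345 line by line, and the 15 pairs of group columns in the pooled table a median of 0.942. For genes with a pooled FPKM of at least 200, a value within 1.5-fold stood on the named line of a library in 8.00% of cases (median over libraries) and within 10 lines in 58.4%, against 17.3% for lines 2000 away. In simulated libraries of 33201 genes made from differentiated cells, shuffling within 20 lines took the correlation from 0.988 to 0.155 and left it at 1 over 500 lines. Lines were not matched by value, which would have built in the agreement of replicates. No library columns were left unused, and no pair held identical sorted values.

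The authors' q-values therefore replace the planned tests. A gene was called where q was under 0.05 and FPKM at least 1 in 1 or both of the compared groups. The q floor of 0.000551 means that genes at it cannot be ranked by q. The ratio of meristematic to differentiated constructs was turned in sign from the deposited direction. A ratio against a group listed at 0 was left out of medians and the call kept; 14 genes were listed at 0 in 1 group and at an FPKM of 10 or more in the other 5, 8 of them at 0 in meristematic cells, which can be a failed estimate. Whether an effect of printing differed between tissues was not tested, because the table gives no error per gene. The labels do not say how libraries relate to plants, and the series speaks of independent experiments; p-values of permutation tests measure the spread between these libraries.

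Before the data were examined, the groups, the comparisons, 27 gene lists, the rule for named genes and the other settings to be tried were set. The rule names, per comparison, the 6 highest and 6 lowest log2 ratios among called genes with a symbol and an FPKM of at least 10 in the higher group, up to 4 members with the smallest q for each list described, any member given only as a value, SCR and the reference genes. Its condition that libraries must not overlap between groups could not be applied. Ties in q were broken by the size of the ratio. Some genes that meet the rule are not reported. Members named for contrast, such as those against their list's direction, were chosen after their values were seen. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins (seed 20); this percentile describes the pooled values and is not a test. Counts adjusted over the list alone could not be had, as the table gives no unadjusted p. In a simulation, the 17563 genes of the printing comparison in differentiated tissue were given independent random values with the overall spread of the deposited ratios. Of 200 unchanged lists of 14 genes, 2% lay beyond the central range, and 99% of 200 lists shifted by 1 on the log2 scale lay above it. Members of real lists can change together, which the simulation leaves out. It therefore does not show how often a real unchanged list would lie beyond that range.

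For each library, summed FPKM, genes at an FPKM of at least 1 and the share of the 10 highest values were computed, which do not need exact lines. The share at lines named for organelle genes was also computed. It does depend on lines, and as values can stand some lines from their gene, it is approximate. All these measures were compared with exact two-sided permutation tests, adjusted by Benjamini-Hochberg over 28 tests. The smallest p is 0.1 for 3 against 3 libraries and 0.2 for 2 against 3. Overlaps were tested with Fisher's exact test, which takes genes as independent, so its p-values measure no spread between libraries. Alternatives were other FPKM minimums (none and 5), an absolute log2 ratio of at least 1, pseudocounts of 0.1 and 5, and TPM rescaling, quantile normalization and median-ratio factors of the group columns. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.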

Results

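RNA was sequenced from Arabidopsis thaliana root cells, either as isolated cells or after the cells had been bioprinted. In bioprinting, living cells are mixed into a printable material and deposited by a machine in a set shape, here called a construct. The plants carried pSCR:SCR-mCherry, a fusion of the red fluorescent protein mCherry to SCARECROW (SCR), a transcription factor of the root endodermis and stem cell niche, under the SCR promoter. Cells came from root tissue labelled meristematic or differentiated, and the series describes the isolated cells as the control. The 17 libraries fell into 6 groups. Isolated cells at day 0 had 3 libraries from differentiated and 3 from meristematic tissue, constructs at day 0 had 3 from each tissue, and constructs of differentiated tissue had 3 libraries at day 1 and 2 at day 3.

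Expression was given as FPKM, fragments counted per length of transcript and scaled to the number of mapped fragments. FPKM values carry no read totals, so the depth of each library is unknown. Summed FPKM per library ran from 671184 to 996810, and 14756 to 16946 genes per library had an FPKM of at least 1. The highest sum and the fewest genes were both in replicate 3 of meristematic cells, where the 10 highest values held 8.34% of the sum against 4.61% and 4.13% in replicates 1 and 2; pooled values without it could not be had. The values per gene below come from the authors' deposited table, which holds 1 pooled FPKM per group and, for 7 comparisons between groups, a log2 ratio and a q-value. Pooled FPKM summed to between 741440 in constructs at day 3 and 1234075 in meristematic cells. The latter sum lay above that of each library of its group, so pooled values are not plain means of the library values. A gene was called changed where that q was under 0.05 and the FPKM was at least 1 in at least 1 of the compared groups. No SD per gene could be given, because the library columns do not hold the same gene in the same place. The smallest q was 0.000551 in each of the 7 comparisons, and it applies to every gene said below to pass, rise or fall unless another q is given.

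SCR (AT3G54220) itself, whose promoter and coding sequence the transgene uses, had in the authors' deposited table a pooled FPKM of 12.4 in differentiated cells, 12.1 in differentiated constructs at day 0, 11.6 at day 1 and 14.8 at day 3. In meristematic tissue the authors' deposited table gave SCR at 7.74 in isolated cells and 6.88 in constructs. Of the 7 comparisons in the authors' deposited table, SCR passed the threshold only between constructs of both tissues, where it was lower in the meristematic ones (log2 ratio -0.81, q 0.0397).

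The first comparison asked what differed between bioprinted and isolated cells at day 0, in differentiated tissue. Genes for heat shock proteins, chaperones that hold or refold damaged proteins, were the most raised group in the constructs. HSP18.2 (AT5G59720), a small heat shock protein, rose from a pooled FPKM of 33.9 in isolated cells to 478 in constructs, a log2 ratio of 3.82 in the authors' deposited table. Some genes of root hairs and of wall loosening were lower, among them EXPA18 (AT1G62980), a root hair expansin, which fell from 57.1 to 11.6 (log2 ratio -2.30) in the authors' deposited table. By the authors' q-values, 2198 of 17654 genes were called, 896 higher and 1302 lower in constructs.

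Besides HSP18.2, the genes raised most in differentiated constructs were the mitochondrial RNA editing factor MEF1 (AT5G52630), at a log2 ratio of 3.62 in the authors' deposited table, and 4 chaperone genes. These were the co-chaperone BAG6 (AT2G46240) at 3.57, the mitochondrial small heat shock protein HSP23.6-MITO (AT4G25200) at 3.44, ATHSP22.0 (AT4G10250) at 3.43 and the disaggregase CLPB4 (AT2G25140) at 3.25 in the authors' deposited table. MEF1 has the locus number next to that of HSP90.1 (AT5G52640), a heat shock gene at 3.01 in the authors' deposited table. Whether reads of 1 were counted for the other is not known, so the MEF1 value is uncertain. The genes lowered most in the authors' deposited table included ORA47 (AT1G74930), an activator of jasmonate synthesis genes, at -2.48 and CBF2 (AT4G25470), a cold response factor, at -2.29. CAF1a (AT3G44260), which shortens mRNA poly(A) tails, stood at -2.21, CID5 (AT5G11440) at -2.35 and the wall enzyme gene XTH12 (AT5G57530) at -2.17 in the authors' deposited table.

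Of the 16 measured members of the heat shock list, 15 rose in differentiated constructs and none fell; the list's median log2 ratio was 2.98, at percentile 100 among random lists of matched expression. The exception in the authors' deposited table was DREB2A (AT5G05410), a drought and heat regulator, with a log2 ratio of -0.09. Sugar starvation genes, which respond to darkness and lack of sugar, had 4 of 9 members higher and a median of 0.89. They were DIN2 (AT3G60140) at 2.12, DIN10 (AT5G20250) at 1.16 (q 0.0115), TPS11 (AT2G18700) at 1.09 (q 0.0139) and ASN1 (AT3G47340) at 0.99 (q 0.0394) in the authors' deposited table. Root hair genes had 3 of 8 members lower and none higher, with a median of -0.74. Besides EXPA18 these were COBL9 (AT5G49270) at -1.73 and EXPA7 (AT1G12560) at -0.74 (q 0.0493) in the authors' deposited table. Among expansins and xyloglucan enzymes, which loosen walls, 6 of 17 fell, including EXPA17 (AT4G01630) at -1.79, XTH4 (AT2G06850) at -1.41 and XTH17 (AT1G65310) at -1.40 in the authors' deposited table. EXPA4 (AT2G39700), of the same list, rose by 1.24 (q 0.00144) in the authors' deposited table.

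Other lists had few members called in differentiated constructs. Of 14 G1 regulators, 3 fell, CYCD4;1 (AT5G65420) at -2.27 (q 0.0112), KRP2 (AT3G50630) at -1.16 (q 0.00387) and CDC2 (AT3G48750) at -0.81 (q 0.0397), while E2FB (AT5G22220) rose by 1.27 (q 0.00144) in the authors' deposited table. BRN1 (AT1G33280) and BRN2 (AT4G10350), NAC factors of the root cap, fell with ratios of -0.87 (q 0.0271) and -1.74 in the authors' deposited table. The median of the hypoxia list was 0.50, above that of most random lists (percentile 99.5), yet its 2 called members of 12 fell, HB1 (AT2G16060) at -1.22 (q 0.00144) and HRE2 (AT2G47520) at -0.91 (q 0.0326) in the authors' deposited table. Wound and regeneration regulators went both ways, with 1 of 19 higher and 2 lower; WIND1 (AT1G78080) stood at 1.15 (q 0.00538) and RRTF1 (AT4G34410) at -0.92 (q 0.0311) in the authors' deposited table. Lignin, xylem, mitotic, primary wall, meristem, suberin, phloem, pericycle, senescence and auxin lists had no member called, and neither had the reference genes. Of the remaining lists, ribosome biogenesis and DNA replication had 1 member higher each and none lower, jasmonate and immune lists 1 higher and 1 lower each, the oxidative list 2 lower, and Casparian strip, photosynthesis and cytokinin lists 1 lower each.

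In meristematic tissue the same comparison also had heat shock genes higher in constructs. HSP21 (AT4G27670), a chloroplast small heat shock protein, rose from a pooled FPKM of 34.2 to 170.2 (log2 ratio 2.32) in the authors' deposited table, and CLPB4 from 22.8 to 121 (2.41). Several root hair genes were lower, led by RHS13 (AT4G02270), which went from 157 to 31.4 (-2.32) in the authors' deposited table. By the authors' q-values, 1823 of 17561 genes were called, 326 higher and 1497 lower.

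The other genes raised most in meristematic constructs were ATHSP22.0 at 2.22, the hydrogen peroxide scavenger APX2 (AT3G09640) at 2.35 (q 0.00144), FKBP53 (AT4G25340), a nuclear prolyl isomerase, at 2.09 and MIPS2 (AT2G22240), an enzyme of inositol synthesis, at 2.06 in the authors' deposited table. Lowest in the authors' deposited table were GIP2 (AT1G73790), a small protein of microtubule nucleation, at -2.78, the signalling peptide genes RALF23 (AT3G16570) at -2.27 and CLE1 (AT1G73165) at -2.18, the deadenylase CAF1b (AT5G22250) at -2.24, and EXPA18 at -2.08. Of the heat shock list, 11 of 16 members rose and none fell, with a median of 1.67 at percentile 100. Its members included ROF2 (AT5G48570) at 2.09 and HSP18.2 at 1.89, while HSP101 (AT1G74310) at 1.55 and HSP90.1 (AT5G52640) at 1.62 did not pass, in the authors' deposited table. Root hair genes fell in 5 of 8 cases and rose in none (median at percentile 0.0700), among them COBL9 at -1.48 (q 0.00418), the root hair growth regulator RSL4 (AT1G27740) at -1.20 (q 0.00509) and EXPA7 at -1.04 (q 0.00678) in the authors' deposited table.

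The Casparian strip, the lignin belt of the endodermis, had 3 of 9 genes lower in meristematic constructs. Among them were its membrane proteins CASP2 (AT3G11550) at -1.12 (q 0.010) and CASP5 (AT5G15290) at -1.02 (q 0.0266) in the authors' deposited table. DIN2 was the 1 sugar starvation gene of 9 that rose, at 1.03 (q 0.0359), and HB1 and HRE2 of the hypoxia list were lower, at -0.96 (q 0.0210) and -1.08 (q 0.0144), in the authors' deposited table. Of 17 wall loosening genes 3 fell, and of 16 jasmonate genes 2 fell. Wound regulators had 1 member higher, LBD16 (AT2G42430) at 0.99 (q 0.0141) in the authors' deposited table, and 2 lower. The cytokinin list had 1 higher and 1 lower, and G1, meristem, non-hair and root cap (1 joint list), pericycle, oxidative and senescence lists had 1 member lower each. None of the members of the other 12 lists was called.

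Constructs differed from isolated cells in the same genes in both tissues more often than independent lists would. Of 16916 genes tested in both, 219 were higher in both constructs against 15.5 from independent lists of the same sizes (Fisher's exact test, two-sided p 6.2e-220), 583 were lower in both against 113 (p 5.2e-304), and 0 were called in opposite directions. Across the 15583 genes at an FPKM of at least 1 in all 4 groups the log2 ratios had a Pearson r of 0.687 and a Spearman rho of 0.704; genes are not independent replicates. The groups shared no libraries. Small heat shock genes have near-identical copies, so their single values are uncertain. Whether an effect differed between tissues was not tested. The median log2 ratio of all tested genes was -0.12 in differentiated and -0.14 in meristematic tissue. The share of higher genes among 2-fold calls depended on scaling. In differentiated tissue it was 39.7% as deposited (565 of 1422), 49.3% after rescaling to TPM (698 of 1416), 49.2% after quantile normalization (680 of 1382) and 46.7% with median-ratio factors (664 of 1422). In meristematic tissue it was 16.1% as deposited (224 of 1390), 39.6% after rescaling to TPM (316 of 798), 32.5% after quantile normalization (279 of 858) and 23.0% with median-ratio factors (270 of 1173).

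**Figure D1:**
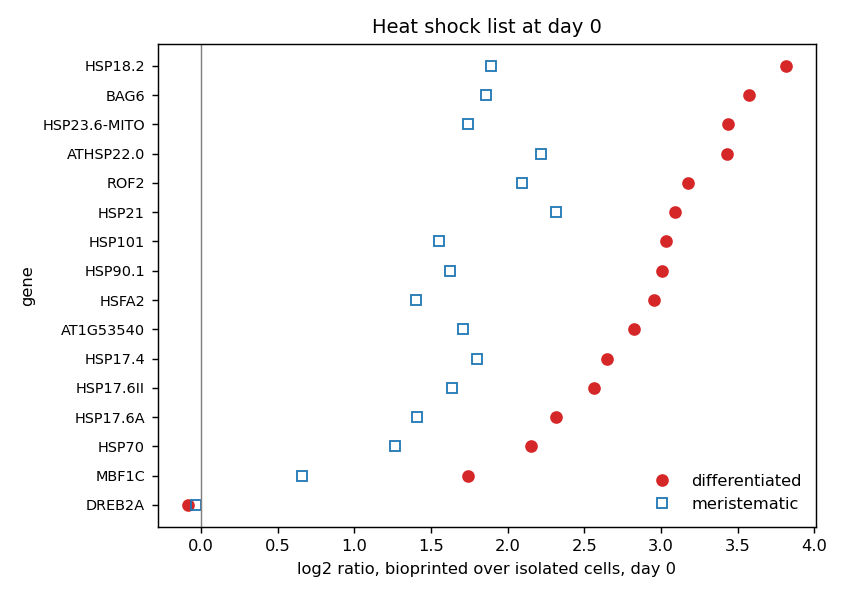
Log2 ratio of pooled FPKM, bioprinted over isolated cells at day 0 (x axis), for each gene of the heat shock list (y axis), from the authors' deposited table. Filled circles are differentiated and open squares meristematic tissue; all but DREB2A lie to the right of 0 in both tissues, and the medians are 2.98 and 1.67.

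Among the libraries, the share of summed FPKM at positions named for chloroplast and mitochondrial genes was compared as well. It was 0.310% ± 0.0599 (SD, n = 3) in differentiated cells and 1.35% ± 0.825 (SD, n = 3) in differentiated constructs. The difference of 1.04 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.7 over 28 tests of library measures). In meristematic tissue the share was 0.545% ± 0.10 (SD, n = 3) in cells and 1.35% ± 0.710 (SD, n = 3) in constructs, a difference of 0.803 points (exact p 0.1, adjusted 0.7). Each of the 3 construct libraries lay above each of the 3 cell libraries in both tissues. Such separation was not particular to constructs. Among isolated cells, each meristematic library lay above each differentiated one, by 0.235 points in the mean (exact permutation p 0.1, adjusted 0.7). At day 1 the share was 2.1% ± 1.20 (SD, n = 3), and at day 3 it was 2.03% ± 1.26 (SD, n = 2). Neither differed from day 0 beyond the spread (exact permutation p 0.4 and 0.6, adjusted 0.988 each). These shares are approximate, since values can stand some lines from their gene. From the pooled values, the share was 0.318% in differentiated cells, 0.435% in meristematic cells and 1.36% in meristematic constructs. In differentiated constructs it was 1.42% at day 0, 0.947% at day 1 and 2.11% at day 3. The pooled share was thus lower at day 1 than at day 0, against the library means.

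**Figure D2:**
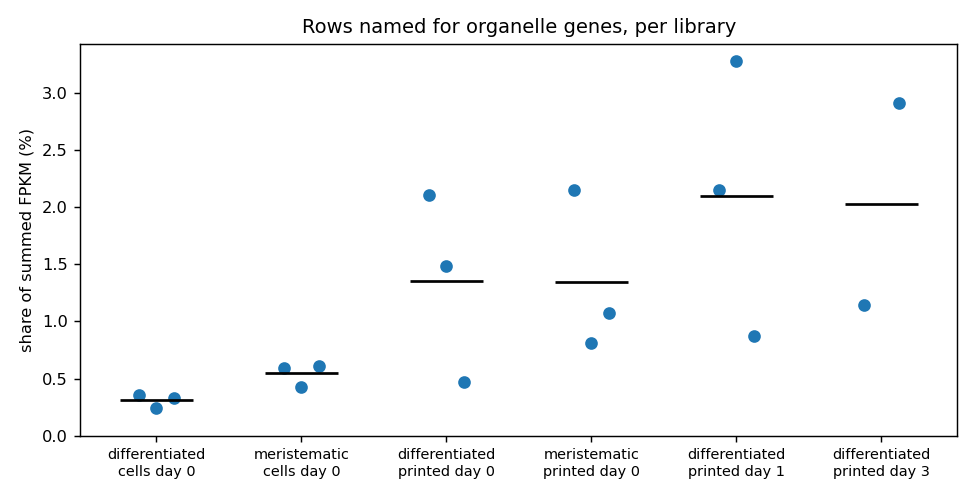
Share of summed FPKM (%, y axis) at positions named for organelle genes in each library, by group (x axis). Points are libraries and lines group means; isolated cells lie between 0.242 and 0.613%, constructs between 0.470 and 3.28%.

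The next comparison set tissue labelled meristematic against tissue labelled differentiated, among isolated cells. Several genes of the nucleolus, where ribosomes are assembled, and several regulators of the root meristem were lower in the cells labelled meristematic. FIB2 (AT4G25630), a fibrillarin that modifies ribosomal RNA, had a pooled FPKM of 4.77 in meristematic and 24.9 in differentiated cells (log2 ratio -2.38) in the authors' deposited table. Several genes of programmed cell death and the root cap were higher, such as the ribonuclease RNS3 (AT1G26820) at 89.1 against 21.8 (2.03) in the authors' deposited table. By the authors' q-values, 1365 of 17623 genes were called, 816 higher and 549 lower in meristematic cells.

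The genes with the highest ratios in the authors' deposited table were the cis-prenyltransferase gene CPT (AT2G23410) at 2.70, EDA36 (AT4G13890) at 2.56, the carboxylesterase CXE18 (AT5G23530) at 2.47, the fatty acid desaturase ADS1 (AT1G06080) at 2.40 and the beta-glucosidase BGLU34 (AT1G47600) at 2.07. The lowest in the authors' deposited table were the glycine-rich protein gene GRP9 (AT2G05440) at -3.63, the nucleolar histone deacetylase HDA3 (AT3G44750) at -2.66, MIPS1 (AT4G39800) of inositol synthesis at -2.39, the RNA-binding GRP4 (AT3G23830) at -2.26 and the peroxidase Prx37 (AT4G08770) at -2.14. Of 14 ribosome biogenesis genes 8 fell and 1 rose (median -1.15, percentile 0); CBF5 (AT3G57150), a pseudouridine synthase, stood at -1.96 and the nucleolin NUC-L2 (AT3G18610) at 1.46 (q 0.00323) in the authors' deposited table. Root meristem regulators had 5 of 13 lower and none higher (median -1.02, percentile 0). The embryo and meristem factor BBM (AT5G17430) was at -2.61 (q 0.0163), PLT1 (AT3G20840) at -1.88 (q 0.0283) and SHR (AT4G37650), which acts upstream of SCR, at -1.02 (q 0.0401) in the authors' deposited table. DNA replication genes fell in 2 of 14 cases (median -0.83), MCM2 (AT1G44900) at -1.44 (q 0.0220) and PCNA1 (AT1G07370) at -1.42 (q 0.0246) in the authors' deposited table.

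Of 8 senescence and cell death genes, 5 rose and none fell (median 1.39, percentile 100), including the metacaspase MC9 (AT5G04200) at 1.91 and the nuclease BFN1 (AT1G11190) at 1.59 in the authors' deposited table. BRN1 and BRN2 of the root cap rose, at 1.18 and 1.27, while SMB (AT1G79580), a further root cap factor, was at 0.88 and did not pass, in the authors' deposited table. Heat shock genes were higher in 4 of 16 cases (median 0.86), HSP18.2 at 1.52 (q 0.00102) and BAG6 at 1.45 (q 0.0161) in the authors' deposited table. Hypoxia and jasmonate lists had 3 members higher each and none lower, root hair and wound lists 2 higher each, sugar starvation and auxin lists 1 higher each, and wall loosening 2 higher and 2 lower. The immune list had 2 lower and the cytokinin list 1 lower, and no member of the other 12 lists was called, mitotic and G1 regulators included.

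The tissues were also compared among constructs at day 0. Ribosome biogenesis genes fell in 10 of 14 cases in meristematic constructs and rose in none (median -1.12, percentile 0), with FIB2 at -2.54, CBF5 at -2.49 and NOP56 (AT1G56110) at -2.08 in the authors' deposited table. BRN2 rose from a pooled FPKM of 6.85 in differentiated to 33.9 in meristematic constructs (log2 ratio 2.31), and BRN1 by 1.28, in the authors' deposited table. The authors' deposited table gives this comparison as differentiated over meristematic, and its sign is turned here. By the authors' q-values, 1653 of 17627 genes were called, 840 higher and 813 lower.

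Highest besides BRN2 in the authors' deposited table were ADS1 at 3.69, CPT at 3.35, the peptide gene CLE14 (AT1G63245) at 2.67 (q 0.00858), the acyltransferase GPAT2 (AT1G02390) at 2.28 and the lipid transfer protein LTP5 (AT3G51600) at 2.27. Lowest besides FIB2 and CBF5 in the authors' deposited table were HDA3 at -2.51, MIPS1 at -2.47, the ribosome-bound scaffold RACK1C_AT (AT3G18130) at -2.28 and the ribosomal protein RPL16A (AT2G42740) at -2.28 (q 0.00102). Meristem regulators fell in 5 of 11 cases (median -1.01), JKD (AT5G03150) at -1.48 (q 0.00221), SHR at -1.46 (q 0.0124) and BBM at -2.84 (q 0.0173) in the authors' deposited table, and DNA replication genes in 4 of 13 (median -1.13). Senescence genes rose in 4 of 8 cases (median 0.79), MC9 at 1.86 in the authors' deposited table. Among wall loosening genes 5 of 17 rose and 3 fell, XTH23 (AT4G25810) at 1.72 and EXPA4 at -1.93 in the authors' deposited table.

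Of the heat shock list 0 of 16 members were called between constructs by the authors' q-values, and its median was -0.39. Mitotic genes had 1 higher, the kinase AUR2 (AT2G25880) at 1.57 (q 0.0189), and 1 lower, CDKB1;1 (AT3G54180) at -1.39 (q 0.0435), in the authors' deposited table. The oxidative list had 3 members higher, hypoxia and photosynthesis lists 2 each, and G1, wound, xylem, jasmonate and auxin lists 1 each, with none lower. Cytokinin genes had 1 higher and 3 lower and immune genes 1 lower, and no member of the other 9 lists was called.

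Both tissue comparisons shared more calls than independent lists would. Of 16951 genes, 357 were higher in the meristematic group in both against 38.2 from independent lists (Fisher's exact test, two-sided p 2.8e-279), 350 were lower in both against 23.9, and 1 was called in opposite directions. Log2 ratios over 15583 genes had a Pearson r of 0.622 and a Spearman rho of 0.568, and the groups shared no libraries. Genes are not independent replicates, so the p-value measures no spread between libraries. The median of all tested genes was 0.12 among isolated cells, where the share of higher genes among 2-fold calls was 59.0% as deposited (589 of 998), 31.8% after rescaling to TPM (256 of 804), 45.4% after quantile normalization (395 of 871) and 53.5% with median-ratio factors (526 of 984); among constructs it was 47.6% as deposited and 41.6%, 45.1% and 46.4% under the same 3 scalings.

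**Figure D3:**
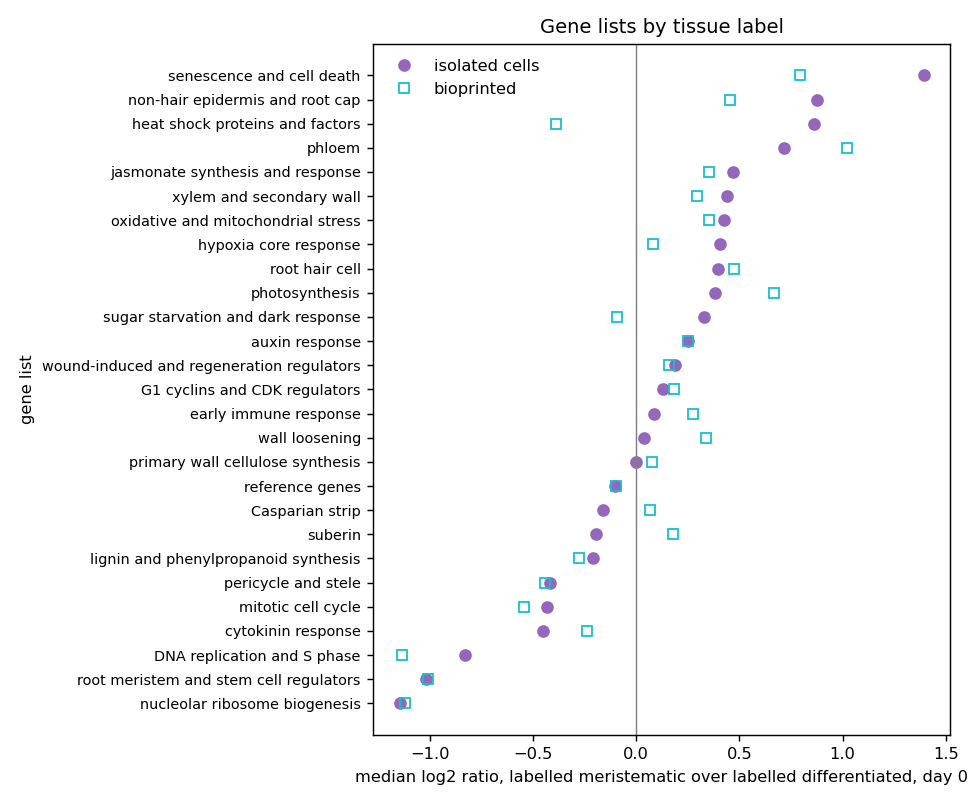
Median log2 ratio of each list's measured members, tissue labelled meristematic over tissue labelled differentiated at day 0 (x axis), by gene list (y axis). Filled circles are isolated cells and open squares constructs; ribosome biogenesis lies at -1.15 and -1.12 and senescence at 1.39 and 0.79, and the G1, primary wall, wall loosening, wound, immune, auxin and Casparian strip lists change side with the scaling between groups in at least 1 of both comparisons.

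The last comparisons followed constructs of differentiated tissue from day 0 to day 1 and day 3. At day 1, most genes of jasmonate, the hormone of wounding, had fallen, and several genes of suberin, the waxy polymer of the mature endodermis and wound periderm, had risen. LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, went from a pooled FPKM of 31.1 to 1.88 (log2 ratio -4.05), and CYP86B1 (AT5G23190), a fatty acid hydroxylase of suberin, from 0.181 to 9.37 (5.69) in the authors' deposited table. Ribosome biogenesis genes rose as well, with FIB2 from 23.5 to 71.5 (1.60) in the authors' deposited table. By the authors' q-values, 5865 of 17993 genes were called, 2917 higher and 2948 lower at day 1.

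The genes raised most at day 1 in the authors' deposited table were EARLI1 (AT4G12480), a lipid transfer-like wall protein, at 7.67, the RNA-binding PUM9 (AT1G35730) at 7.47, MAKR4 (AT2G39370) at 6.88 (q 0.00418), the peptide gene GASA5 (AT3G02885) at 6.49, the secreted peroxidase PRXCB (AT3G49120) at 6.49 and the lectin JAL22 (AT2G39310) at 5.93. PRXCB reached a pooled FPKM of 2782 from 31.0 in the authors' deposited table. Those lowered most in the authors' deposited table were the peptide gene CLE2 (AT4G18510) at -5.25 (q 0.0185), the wall enzyme XTH21 (AT2G18800) at -5.18 (q 0.00183), the heat shock factor HSFA6B (AT3G22830) at -4.91, the drought and cold gene LTI78 (AT5G52310) at -4.61, sks16 (AT2G23630) at -4.57 and the phloem sucrose carrier SUC2 (AT1G22710) at -4.39.

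Of 17 jasmonate genes 15 fell and none rose (median -2.73, percentile 0), among them LOX4 (AT1G72520) at -3.75, AOC3 (AT3G25780) at -3.27 and the repressor JAZ5 (AT1G17380) at -3.20 in the authors' deposited table. Suberin genes rose in 6 of 11 cases (median 3.87), also ASFT (AT5G41040), a feruloyl transferase, at 4.92, GPAT5 (AT3G11430) at 4.75 (q 0.00102) and FAR5 (AT3G44550) at 2.30 (q 0.00144) in the authors' deposited table. Ribosome biogenesis genes rose in 13 of 14 cases (median 1.40), APUM24 (AT3G16810) at 1.97 and NUC-L2 at 1.81 in the authors' deposited table. DNA replication genes rose in 7 of 15 (median 1.21), led by the ribonucleotide reductase genes RNR1 (AT2G21790) at 2.16 and TSO2 (AT3G27060) at 1.80 in the authors' deposited table. Of 10 mitotic genes 5 fell and none rose, CDC20.1 (AT4G33270) at -1.83 (q 0.00757) and the cytokinesis syntaxin KNOLLE (AT1G08560) at -1.79 (q 0.00981) in the authors' deposited table. Only 1 mitotic gene had an FPKM of at least 5 at day 0 or day 1, and it was not called. Vascular genes fell, 6 of 9 for xylem (median -1.82) and 3 of 4 for phloem (median -3.24). The secondary wall cellulose synthases CESA4 (AT5G44030) at -1.96 and CESA8 (AT4G18780) at -1.88 and the phloem regulator APL (AT1G79430) at -2.74 were among them in the authors' deposited table, while VND6 (AT5G62380), a master regulator of xylem vessels, rose by 2.89 (q 0.00932).

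Wall genes split at day 1. Wall loosening genes fell in 9 and rose in 3 of 17 cases (median -1.87), XTH19 (AT4G30290) at -3.42 against EXPA10 (AT1G26770) at 4.12 and EXPA4 at 3.47 in the authors' deposited table, and primary wall cellulose genes fell in 7 of 9 cases (median -1.02). Heat shock genes fell in 6 of 16 cases, HSFA2 (AT2G26150) at -3.30 and BAG6 at -2.89, and HSP18.2 rose further by 1.19 (q 0.0319) in the authors' deposited table. Wound and regeneration regulators had 4 higher and 4 lower of 17, with the root founder cell factors LBD29 (AT3G58190) at 3.31 and WOX11 (AT3G03660) at 2.40 (q 0.00221) and the wound factor RRTF1 at -2.95 in the authors' deposited table. In the immune list, CYP81F2 (AT5G57220) of indole glucosinolates rose by 4.05 and PAD3 (AT3G26830) of camalexin synthesis by 3.82, and WRKY40 (AT1G80840) stood at -3.97 in the authors' deposited table; 3 of 14 rose and 5 fell. WOX5 (AT3G11260), the quiescent centre factor, was at -1.69 (q 0.00221) in the authors' deposited table; of 11 meristem regulators 1 rose and 3 fell.

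At day 3 over day 0, EARLI1 reached a pooled FPKM of 334 from 0.989 (log2 ratio 8.40) in the authors' deposited table. Jasmonate genes fell in 16 of 17 cases (median -3.97), ribosome biogenesis genes rose in 13 of 14 (median 2.37), DNA replication genes in 13 of 15 (median 2.30) and suberin genes in 8 of 11 (median 4.57). By the authors' q-values, 7761 of 18372 genes were called over day 0, 3867 higher and 3894 lower.

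Highest at day 3 after EARLI1 in the authors' deposited table were GASA5 at 7.49 (q 0.00183), NDB4 (AT2G20800), a mitochondrial NAD(P)H dehydrogenase, at 7.26, JAL22 at 7.15, ACL5 (AT5G19530), which makes thermospermine, at 7.11 and the suberin hydroxylase CYP86A1 (AT5G58860) at 6.91 (q 0.0139). Lowest in the authors' deposited table were the ubiquitin ligase PUB19 (AT1G60190) at -7.73 (q 0.0454), RHS19 (AT5G67400) of root hairs at -7.35 (q 0.0181), the auxin synthesis gene TAA1 (AT1G70560) at -7.11 (q 0.0181), ERF13 (AT2G44840) at -7.09, sks16 at -6.69 (q 0.0314) and CYCP3;2 (AT3G60550) at -6.54 (q 0.0105). The jasmonate repressors JAZ9 (AT1G70700) and JAZ10 (AT5G13220) were at -5.70 and -4.96 in the authors' deposited table, and VSP1 (AT5G24780) alone of that list rose, by 2.67 (q 0.00102). TSO2 rose by 4.01, RNR1 by 3.88 and the replicative helicase subunit MCM3 (AT5G46280) by 3.09 in the authors' deposited table, whereas of 10 mitotic genes 1 rose and 3 fell, CDKB1;1 at 1.81 (q 0.00144) and CYCA2;3 (AT1G15570) at -3.00 (q 0.0212). G1 regulators had 3 higher and 1 lower of 13, CDC2 at 1.55 and the retinoblastoma homologue RBR1 (AT3G12280) at 1.52 in the authors' deposited table.

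At day 3 Casparian strip genes fell in 8 of 9 cases (median -2.48), MYB36 (AT5G57620), their activator, at -3.93 and CASP1 (AT2G36100) at -3.01 in the authors' deposited table; root hair genes in 6 of 8 (median -2.17), PRP3 (AT3G62680) at -3.97; xylem genes in 6 of 9 (median -3.51), CESA8 at -5.40. Phloem genes fell in 3 of 4 cases, SUC2 at -6.39 in the authors' deposited table; root cap and non-hair genes in 3 of 5, and pericycle genes in 2 of 4. Sugar starvation genes fell in 7 and rose in 1 of 9 cases (median -2.21), DIN10 at -3.87 and ASN1 at -3.47, with DIN2 rising by 1.21 (q 0.0387) in the authors' deposited table. Heat shock genes fell in 8 and rose in 1 of 16 cases (median -1.82), HSFA2 at -5.51 in the authors' deposited table. WOX11 rose by 4.35, while WOX5 was at -3.23 and UPB1 (AT2G47270), which controls the meristem's end, at -4.00 in the authors' deposited table. Wound regulators had 4 higher and 7 lower of 21, and meristem regulators 2 and 5 of 12.

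For the remaining lists at day 1, hypoxia genes rose in 4 of 12 cases, sugar starvation had 1 higher and 3 lower, auxin 3 and 2, lignin 2 and 2, and G1 and cytokinin lists 2 higher each. Oxidative and senescence lists had 3 lower each, root hair, pericycle and the joint non-hair and root cap lists 2 lower each, and Casparian strip and photosynthesis lists 1 lower each. At day 3 hypoxia had 5 higher and 1 lower, led by SUS4 (AT3G43190) at 2.23 in the authors' deposited table, lignin 1 and 6, immune 3 and 6, wall loosening 6 and 8, auxin 3 and 1, oxidative 1 and 3, and cytokinin 1 and 1. Primary wall genes had 7 lower, senescence 5 and photosynthesis 1. Reference genes were not steady: ACT2 (AT3G18780) went from a pooled FPKM of 463 at day 0 to 239.8 (q 0.0431) and 90.6, and GAPC1 (AT3G04120) rose by 1.26 (q 0.0360) and 1.45 (q 0.0423) in the authors' deposited table. UBQ10 (AT4G05320), PP2AA3 (AT1G13320) and UBC21 (AT5G25760) passed at neither day in the authors' deposited table.

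Between day 1 and day 3, 2528 of 17611 genes were called by the authors' q-values, 1035 higher and 1493 lower at day 3. ESR1 (AT1G12980), a shoot regeneration factor, rose from a pooled FPKM of 0.740 to 27.1 (log2 ratio 5.20), followed by SK14 (AT2G03170) at 4.30 (q 0.0297), the xylogen XYP1 (AT5G64080) at 3.49, the defensin PDF2.1 (AT2G02120) at 3.34, SCRL26 (AT4G22105), a small cysteine-rich protein unrelated to SCARECROW, at 3.34 (q 0.00567) and the cutinase CDEF1 (AT4G30140) at 3.25 in the authors' deposited table. RHS19 at -6.15 (q 0.0181), RTFL12 (AT4G13395) at -4.57 (q 0.00102), the peptide gene RALFL32 (AT4G14010) at -4.22 (q 0.00479), the peroxidase RCI3 (AT1G05260) at -3.91, BGAL4 (AT5G56870) at -3.83 and PRP3 at -3.74 fell most in the authors' deposited table. DNA replication and ribosome biogenesis genes rose in 9 of 15 and 9 of 14 cases and suberin genes in 6 of 12. Casparian strip genes fell in 8 of 9, root hair genes in 7 of 8, sugar starvation genes in 6 of 9 and xylem genes in 6 of 7.

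Of 17700 genes tested at both days, 2289 were higher and 2397 lower at both day 1 and day 3 over day 0, against 591 and 649 from independent lists, and 4 and 2 went in opposite directions. The log2 ratios had a Pearson r of 0.871 and a covariance of 1.37 across 14651 genes. Both comparisons used the same day 0 libraries, so part of the excess may come from the shared controls; unchanged groups could not be simulated without a spread per gene. The share of higher genes among 2-fold calls was 48.8% at day 1, 51.0% at day 3 and 40.8% at day 3 over day 1 as deposited, 56.2%, 57.4% and 47.3% after rescaling to TPM, 48.7%, 52.9% and 44.0% after quantile normalization, and 46.1%, 50.2% and 42.6% with median-ratio factors. Day 3 rests on 2 libraries.

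**Figure D4:**
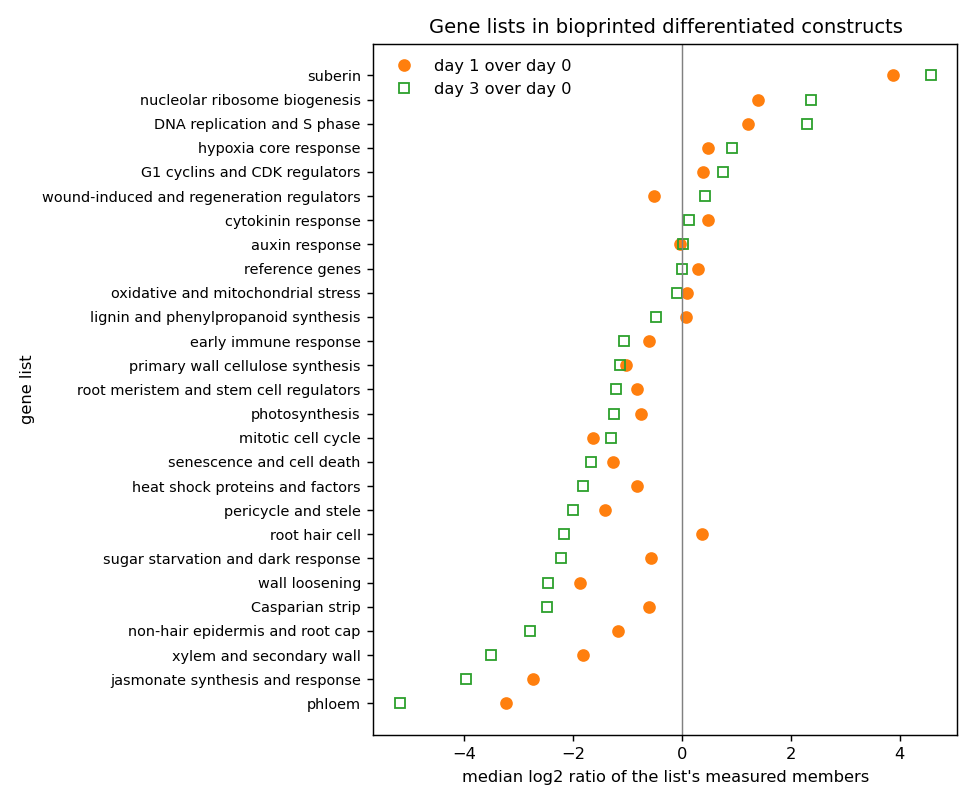
Median log2 ratio of each list's measured members in constructs of differentiated tissue (x axis), by gene list (y axis). Filled circles are day 1 and open squares day 3, each over day 0; suberin lies at 3.87 and 4.57, jasmonate at -2.73 and -3.97, and the auxin, oxidative, reference and lignin lists change side with the scaling between groups at 1 or both days.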

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

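Chosen only after the data were seen were the stricter q, the removal of genes listed at 0, the 2-fold splits, the pseudocount of 1 and both checks of the organelle share. Among counts of called genes over 7 comparisons, 49 of 56 alternative values stayed within 1.5 times the reported one. The authors' q-values were kept under every scaling, so there a count could change only through the FPKM minimum. Whether the calls would hold under another normalization was therefore not tested. An absolute log2 ratio of at least 1 left 1448 genes for printing in differentiated tissue. A q under 0.01 left 904 there, 718 for printing in meristematic tissue, 528 between isolated cells of both tissues, 732 between their constructs, 3805 at day 1 and 1132 between day 1 and day 3; fewer calls follow from a stricter threshold. Shared calls, counted with the same q-values under each scaling, kept within 1.5 times, and the correlations stayed above 0, in 14 of 14 values. Most of these values had little or no room to move. TPM rescaling and median-ratio factors cannot change a correlation, and shared calls could change only where a ratio changed sign. Of 150 list medians, taken relative to all genes under quantile normalization or a pseudocount of 0.1, 148 moved by less than 1.5-fold and 0 reversed; phloem at day 3 moved under both. TPM rescaling and median-ratio factors cannot move a median so taken. Not taken relative to all genes, the medians of 28 of 188 lists and comparisons changed sign under 1 or more scalings, 10 of 27 for printing in meristematic tissue, among them mitotic, DNA replication, wound, immune and oxidative lists. Alternative log2 ratios, not centred, were taken for named genes that were called in the comparison. Of 4896 values, 4430 moved by less than 1.5-fold, 466 by more and 0 reversed. Ratios of genes not called were not counted. A pseudocount cannot reverse a ratio, so only the scalings could have done so, and only among genes already called. Another scaling moved the median log2 ratio of all genes most for printing in meristematic tissue, from -0.14 as deposited to 0.20 under TPM rescaling.

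The organelle share of the libraries kept its direction in 33 of 34 values. Among these, values with replicates as pairs could not differ from the reported ones where both groups had 3 libraries. In differentiated constructs the pooled share was lower at day 1 (0.947%) than at day 0 (1.42%), against the library means. Left out in turn, replicates gave -0.212 to 1.56 percentage points for day 3 over day 0, negative without day 3 replicate 2; the cause was not tested. With replicate numbers as pairs (a replicate block), the difference stays by arithmetic at 1.04 points for printing in differentiated and 0.803 in meristematic tissue. Only the exact p could change, and each was at the smallest that 3 pairs allow, 0.25. Deviations from the group means, taken over windows of 500 lines, had a median correlation of 0.387 between same-numbered libraries of different groups (-0.827 to 0.841, 26 of 40 pairs over 0.1). Between differently numbered ones it was -0.267 (-0.893 to 0.911, 35 of 80 pairs over 0.1). Deviations cancel within a group, so the lower median follows in part from the higher one. The higher median is a hint from the data, not the design; as not every pair passed 0.1, the numbers were not taken to pair the libraries. Not run were fits per gene with a replicate block, each replicate left out, other pseudocounts, array weights or robust variances, camera with an estimated correlation, count-based tools and the test of tissues' difference, all of which need values per gene and library. Depth is unknown, so no limit from it can be given.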

Other observations

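Chosen only after the result was seen were the gene families, the overlap of printing with later days, and all tests of explanations but the one on further root cap genes; the bounds for swapped labels and for low mitotic genes were also revised after their values were seen. Cytosolic ribosomal proteins, taken by their names in the reference, went the way of the ribosome biogenesis genes between tissues and over days: 73 of 171 measured members were lower in meristematic than in differentiated cells and 114 of 173 in constructs (medians -0.79 and -1.05), with none higher. In constructs of differentiated tissue 34 of 171 had risen by day 1 and 134 of 175 by day 3 (medians 0.48 and 1.40), while 1 and 3 fell. Constructs had 55 of 173 lower than isolated cells in meristematic tissue and, in differentiated tissue, 9 of 171; the ribosome biogenesis list had 0 and 1 members called there, with medians above 0 (0.12 and 0.37), and differences between tissues' effects were not tested. Proteasome subunits, which degrade tagged proteins, rose in 15 of 36 cases at day 1 and 17 of 36 at day 3, with none lower.

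Water channels fell with time: 16 of 20 aquaporins were lower at day 1 and 16 of 20 at day 3 (medians -1.39 and -3.14), and 2 and 3 were higher. Arabinogalactan proteins of the cell surface fell in 24 of 37 cases at day 1 and 23 of 37 at day 3, tubulins in 9 and 7 of 13, and late embryogenesis abundant proteins in 24 and 24 of 58, while 6 and 7 of these proteins rose. Cytochrome P450 genes rose in 35 and fell in 20 of 100 cases at day 1, and rose in 36 and fell in 30 of 101 at day 3. None of these medians at day 1 or day 3 changed sign under another scaling. Genes lower after printing in meristematic tissue were also lower at day 3 in differentiated tissue more often than independent lists would be, 531 against 334 of 16682 genes with no shared libraries (Fisher's exact test, two-sided p 2.5e-34). Of those higher after printing, 115 were lower at day 3 against 71.3 (Fisher's exact test, two-sided p 1.75e-08) and 44 were higher against 59.3. Lower after printing and higher at day 3 were 235 against 278. Across 14294 genes the log2 ratios of both comparisons had a Pearson r of only 0.0896, and genes are not independent replicates. In differentiated tissue, printing and day 3 share the day 0 constructs. There 525 against 278 of 17111 genes were lower in both, and 134 against 172 were higher in both. Higher after printing and lower at day 3 were 223 against 204 (Fisher's exact test, two-sided p 0.12), and 150 against 234 were the reverse. The Pearson r there was 0.036 across 14586 genes.

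Most heat shock genes were higher in constructs than in isolated cells in both tissues. The authors' normalization is argued against, since the smaller list median exceeded the largest shift that any scaling gave to all genes by 1.48 on the log2 scale. RNA damage that also raises the organelle share stays open. The heat shock list had a median of -1.82 at day 3 over day 0 while the organelle share of the libraries was 0.676 percentage points higher at day 3, but that difference lay within the spread and was -0.212 without day 3 replicate 2. Printing itself, the difference the design names, stays open as untested.

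Many genes of the meristem and ribosome biogenesis lists were lower in the groups labelled meristematic. The authors' normalization is argued against, since the list median nearer to 0 minus the lowest shift of all genes was -0.825 or lower in both comparisons. Swapped tissue labels stay open, because values go both ways: the 3 measured root cap genes of the tip had a median of at least 1.18 in these groups, against a swap, while root hair genes of mature root had medians of 0.40 among isolated cells and 0.47 among constructs and DNA replication genes -0.83 and -1.13, as a swap would give. More root cap cells in the tissue labelled meristematic may account for part of it: of 5 further root cap genes, listed before their values were seen, the median log2 ratio was 0.930 among isolated cells and 1.03 among constructs, with CEL3, CEL5 and AT1G65570 higher (q at most 0.0159) and ARF10 and ARF16 not past the threshold; CEL3 and ARF10 rose at day 1 and day 3 in differentiated constructs, CEL3 to a pooled FPKM of 638 in the authors' deposited table, while BRN1 fell at both days, so they are not specific to the root cap here, and the other 3 had medians of 0.930 and 1.22. A difference between the tissues themselves stays open as untested.

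Most DNA replication genes rose at day 3 without a rise of the mitotic list over day 0. Normalization is argued against, as the list's median exceeded the largest shift of all genes by 1.92. Whether mitotic genes were too low to show a rise stays open. The 10 measured ones had a median of -1.31 at day 3 over day 0. Of them 3 fell and CDKB1;1 rose, so not all were too low to be called. Only 1 of them, however, had an FPKM of at least 5 at day 0 or day 3, and it rose by 1.81. Over day 1, 5 measured ones had a median of 0.68, with 1 higher and 0 lower. The 1 at an FPKM of at least 5 rose by 1.36 over day 1. More cells in S phase at day 3 than at day 1 stays open. Replication-dependent histones had a median of -0.340 at day 3 over day 1, with 1 of 12 higher and 0 lower. Over day 0 their medians were 0.160 at day 1, with 4 of 12 higher, and 0.228 at day 3, with 2 higher. At both days 0 of these 12 were lower. The wider histone family, taken by names in the reference and not limited to replication-dependent copies, was mixed. At day 3 over day 1 its median was -0.38 (percentile 0.985), with 3 of 48 higher and 3 lower. Over day 0, 12 of 47 were higher and 1 lower at day 1 (percentile 100), and 6 of 47 higher and 4 lower at day 3. The bound that would have excluded more cells in S phase was tightened after the value of -0.340 was seen. The reasons were that histone H4 copies have a high baseline and that none of the 12 replication-dependent histones was called lower. Day itself, the difference the design names, was not tested apart from these.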
